A study of Arabidopsis thaliana with 6 samples.

How the data were processed

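Total RNA of root explants was sequenced on an Illumina system in 6 libraries, 2 for each of WT, arr1 and Pro35SARR1. Groups and replicate numbers come from the sample titles. The series description calls the third genotype AOE, and it was taken as Pro35SARR1 because the other 2 are named alike in both. The submitters' processing notes name CASAVA and DESeq without versions or roles. The aligner, the quantifier, the genome build, the annotation and any use of strand are not given in the sources used here, so overlapping and antisense genes and close paralogs may share reads.

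Per the file headers, the deposited expression table holds an estimated count and an FPKM value for each of 35593 isoforms of 26726 genes in each library. The estimated counts are not raw reads: for genes with 1 isoform and few fragments, 89.9% to 90.9% of the deposited values are whole multiples, within 0.02, of a step that differs between libraries (0.855 to 1.152). Dividing by the step gives 8014081 to 10000859 fragments per library. The authors' deposited table of arr1 against WT gives a p-value adjusted by the authors (FDR), a log2 fold change and a count column that was treated as a score, because for 362 of 437 genes the deposited score lies within 1 of the scaled estimate in all 4 libraries. Every adjusted p-value in the authors' deposited table is at most 0.00983, and every finite log2 value there is at least 1.00 in size. The authors' deposited pathway sheet gives corrected p-values, and a deposited summary gives numbers of called genes, in which both columns carry the same heading. Coordinates are those of the expression table; gene starts lie within 500 bp of a TAIR10.1 annotation for 97.4% of 25934 matched genes.

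Estimated counts of isoforms were summed per gene and rounded. Genes were kept by filterByExpr, scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with 1 mean per genotype, all 6 libraries in the fit and no block, and Benjamini-Hochberg adjusted p-values under 0.05 counted as calls. Of the genes 18083 were tested, with 3 residual degrees of freedom and a common coefficient of biological variation of 0.214. SEs are the log2 fold change divided by the square root of F. CPM values are TMM-scaled. A gene with no counts in a genotype was compared with a floor of 3 counts per library, and floors cover counting error only. On simulated data for arr1 against WT over 18083 genes, 60% of genes changed 4-fold and 7% of genes changed 2-fold were called, with 5 unchanged genes called.

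Before the data were examined, 18 gene lists with 334 genes were fixed, of which 330 are in the table. They cover type-A and type-B response regulators, cytokinin metabolism and transduction, shoot meristem and regeneration, leaf polarity, root meristem and callus, Aux/IAA repressors, auxin synthesis and transport, photosynthesis, cell cycle, root hair, endodermis, xylem and phloem, salicylate and defence, jasmonate, abscisic acid and cold, hypoxia, and flavonoids. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, adjusted over 51 tests of 17 lists in 3 comparisons. The endodermis list had fewer than 5 detected members and was not tested. No list was past the threshold with the correlation estimated per list. That version rests on the few residual degrees of freedom (3 without the block), so adjusted p-values under 0.05 are hard to reach over 51 tests. The type-A list in Pro35SARR1 against WT had an estimated correlation of −0.011, under the preset 0.01. Its unadjusted camera p still rose from 3.98e-05 to 0.0233. A call that ended with an estimated correlation is therefore no measure of correlation alone. A list's median was also taken with genes at 0 in a genotype set to their bound, and without genes under the floor in both. Named genes were fixed by rule. The first part takes ARR1, ARR10, ARR12, WUS, CLV3, STM, IAA17, ARR5, ARR7 and ARR15 always. The second takes, for each comparison with WT, up to 4 called members of each list by adjusted p. The third takes the 5 higher and 5 lower called genes with the largest change, non-overlapping libraries and at least 5 CPM in the higher genotype. For Pro35SARR1 against arr1 only the first part applied. A list of shoot epidermis and cuticle genes and one of thalianol and marneral synthesis genes were written after the main results and before their own values were looked up, leaving out genes already seen. Other genes called in Pro35SARR1 against WT, and the genes the authors set apart, were named after their values were seen.

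Libraries with the same replicate number deviated together from their genotype means: across 14851 genes Pearson's r was 0.395 between WT and arr1, 0.637 between WT and Pro35SARR1 and 0.401 between arr1 and Pro35SARR1, and the second principal component (24.4% of variance) separated the numbers. The labels state no shared batch or day, so the pairing comes from the sample titles' numbers and this check, which was made before calls were compared. The fit with the replicate number as a block is given beside results where it changes a call or moves a count by over 1.5 times. Replicates of a genotype differed by more than sampling noise (chi-square over its degrees of freedom 10.0 to 20.1), so no library was counted as a copy of another.

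Alternatives were DESeq2's size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter, at least 1 CPM in 2 libraries, the block, fits of 2 genotypes, isoforms tested 1 by 1, a log2 fold change of at least 1, limma on log2(FPKM + 1), leaving out each library, and for lists an estimated correlation, fry and the block. Chosen after seeing the data were counts divided by the step, scaling by library totals alone, and the block with an estimated correlation. For shared WT libraries, 40 simulations of unchanged groups were drawn, and after seeing the data 40 with arr1 at its observed means and Pro35SARR1 unchanged. Both kinds were then drawn again with each gene's replicate effect and dispersion from the fit with the block. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for summaries and figures. A second sheet of the pathway file was not used here.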

Results

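RNA was sequenced from Arabidopsis thaliana root explants at the stage when new shoot meristems form. The explants spent 5 days on CIM, a callus-inducing medium, and 7 days on SIM, a shoot-inducing medium with 1 mg/L of the cytokinin N6-(2-isopentenyl)adenine and 0.15 mg/L of the auxin IAA, under continuous light at 22 °C. The 3 genotypes were wild type (WT), the arr1 single mutant and Pro35SARR1, in which the labels place ARR1 behind the 35S promoter. ARR1 is a type-B response regulator, a transcription factor of the cytokinin phosphorelay. Each genotype had 2 libraries, numbered replicate 1 and replicate 2. Nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Total estimated counts were 9012057 and 9381532 in WT. They were 8193313 and 8377273 in arr1, and 8908816 and 9229028 in Pro35SARR1. At this depth 3 counts in each library of WT correspond to 0.338 CPM (counts scaled to the size of the library). Means under that value rest on few counts, so a small SD beside them does not measure precision.

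ARR1 (AT3G16857, chromosome 3, 5755821 to 5759443 in the deposited coordinates) was at 60.6 ± 1.09 CPM in WT (SD, n = 2) and at 1817 ± 130.2 CPM in Pro35SARR1 (SD, n = 2), 29.99-fold higher (log2 fold change 4.91, SE 0.117, adjusted p = 0.000397). In the libraries labelled arr1 it was at 59.9 ± 1.83 CPM (SD, n = 2), a level that differed from WT by less than the spread between replicates (log2 fold change −0.015, SE 0.102, adjusted p = 0.949). Its sign turned positive without arr1 replicate 2 and when libraries were scaled by their totals alone. ARR1 level therefore does not tell the libraries labelled arr1 from WT, and every direction given for arr1 rests on the labels alone. The second annotated ARR1 isoform took 34.4% and 42.2% of the gene's estimated count in the WT libraries, 46.0% and 39.2% in those labelled arr1 and 70.4% and 62.9% in Pro35SARR1. Its close relatives ARR10 and ARR12, also type-B regulators, were not called in either comparison with WT. ARR10 stood at 43.2 ± 8.37 CPM in WT, 40.5 ± 6.24 CPM in arr1-labelled and 35.8 ± 7.01 CPM in Pro35SARR1 libraries. ARR12 stood at 65.6 ± 7.23 CPM, 56.5 ± 4.64 CPM and 62.8 ± 4.73 CPM.

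**Figure D1:**
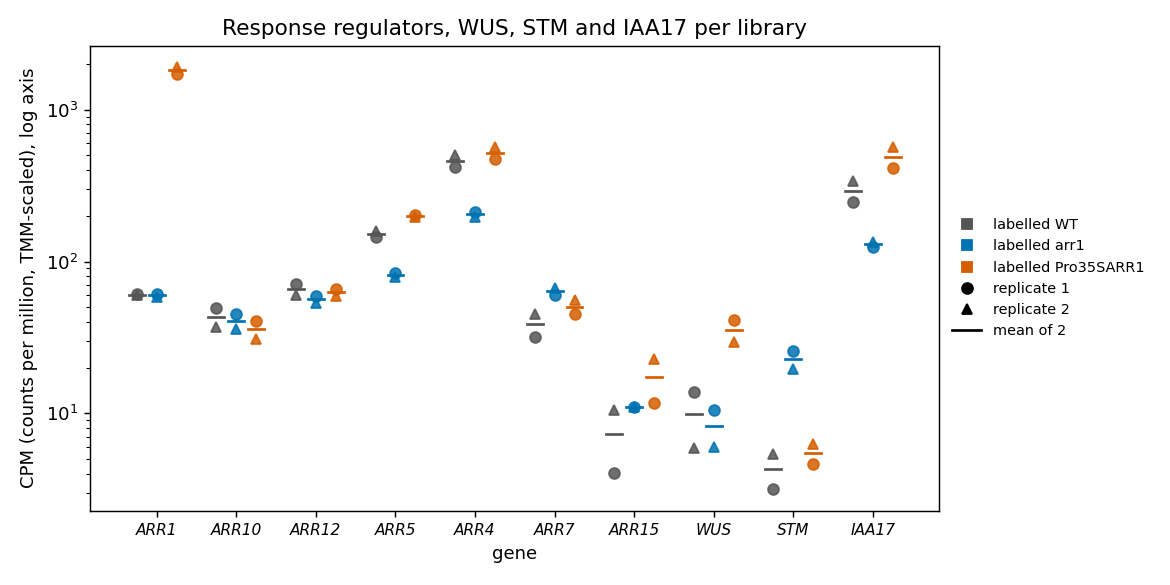
CPM on a log axis for 10 genes in each of the 6 libraries, with a line at the mean of each genotype's 2 libraries. Circles are replicate 1 and triangles replicate 2. ARR1 was at 61.3 and 59.8 CPM in WT, 61.2 and 58.6 CPM in the libraries labelled arr1, and 1725 and 1909 CPM in Pro35SARR1.

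The comparison of arr1 with WT asked how the transcriptome of shoot-forming explants differed in the libraries labelled arr1. In the libraries labelled arr1 FIL, YAB3 and STM were higher. The YABBY gene FIL, of leaf polarity, was at 47.8 ± 8.11 CPM against 1.29 ± 0.714 CPM in WT (log2 fold change 5.19, SE 0.434, adjusted p = 0.0219). The YABBY gene YAB3 was at 30.5 ± 5.71 CPM against 0.675 ± 0.317 CPM (log2 fold change 5.47, SE 0.361, adjusted p = 0.0128). STM, a homeobox gene that maintains the shoot meristem, was at 22.8 ± 4.35 CPM against 4.28 ± 1.58 CPM (log2 fold change 2.41, SE 0.333, adjusted p = 0.0355). The cytokinin-induced type-A response regulators ARR5 and ARR4 were lower. ARR5 fell from 152 ± 9.06 CPM to 81.6 ± 3.82 CPM (log2 fold change −0.89, SE 0.0990, adjusted p = 0.0264). ARR4 fell from 460.0 ± 57.8 CPM to 204 ± 11.9 CPM (log2 fold change −1.17, SE 0.145, adjusted p = 0.0303). All ± values are SDs over n = 2 libraries.

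In all, 198 genes were higher and 343 lower in the libraries labelled arr1 among 18083 tested (edgeR quasi-likelihood test). With the replicate number as a block the counts were 1127 and 1720, and all 541 calls remained. With 1 library left out the counts higher and lower were 15 and 10 without WT replicate 1, 26 and 11 without WT replicate 2, 0 and 0 without arr1 replicate 1, 0 and 0 without arr1 replicate 2, 18 and 5 without Pro35SARR1 replicate 1 and 16 and 5 without Pro35SARR1 replicate 2. Of the calls 36.6% were higher, against 63.0% when libraries were scaled by their totals alone. Of the calls with a change of at least 2-fold 169 were higher and 152 lower. Scaling by totals alone moved the median log2 fold change over all genes by 0.13.

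Among type-A response regulators, feedback repressors of cytokinin signalling, 2 of 10 detected members fell and 0 rose, with 3 lower and 1 higher adjusted over the list alone and 1 higher and 4 lower with the block. Their median log2 fold change was −0.51, or −0.20 with low members at their bound or, where both groups lay under the floor, left out. The list as a whole did not pass its test (camera adjusted p = 0.173, and adjusted p = 0.655 with an estimated correlation). ARR7 was at 63.7 ± 4.46 CPM against 38.7 ± 9.47 CPM in WT (log2 fold change 0.72, SE 0.203, adjusted p = 0.120), and the block gave adjusted p = 0.0142. ARR15 was at 11.04 ± 0.0122 CPM against 7.31 ± 4.60 CPM (adjusted p = 0.547). Of the 31 detected genes of cytokinin metabolism and transduction, 1 rose, CRF2, a cytokinin response factor (log2 fold change 1.397, SE 0.173, adjusted p = 0.0303) and 0 fell. Adjusted over the list alone, 1 was higher, against 4 higher and 3 lower with the block. In the shoot meristem and regeneration list 2 of 21 rose, STM and the receptor kinase gene CLV1 (log2 fold change 1.32, SE 0.199, adjusted p = 0.0392), and adjusted over the list alone 4 were higher and 1 lower, against 4 higher and 2 lower with the block. WUS, the organizer of the shoot meristem, was at 8.24 ± 3.12 CPM against 9.91 ± 5.59 CPM in WT (adjusted p = 0.784), and its sign changed without WT replicate 1 or arr1 replicate 2. CLV3 held at most 4.3 estimated counts in any library and was not tested. In the leaf polarity list 2 of 10 rose, FIL and YAB3, and adjusted over the list alone 4 were higher and 1 lower, against 3 higher and 1 lower with the block. Neither the shoot meristem list (camera adjusted p = 0.0755, and adjusted p = 0.703 with an estimated correlation) nor the leaf polarity list (camera adjusted p = 0.0654, and adjusted p = 0.655 with an estimated correlation) passed its test with all 6 libraries. Both passed as higher with 1 library left out, the first with adjusted p = 0.0103 without WT replicate 2 and adjusted p = 0.0189 without arr1 replicate 2 and the second with adjusted p = 0.0134 without WT replicate 2 and adjusted p = 0.0402 without arr1 replicate 2.

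In the list of auxin synthesis, transport and conjugation 3 of 22 members rose, also 3 adjusted over the list alone, and 0 fell, against 8 higher and 0 lower with the block. The 3 were the efflux carrier gene PIN2 (log2 fold change 2.62, SE 0.232, adjusted p = 0.0219) and the aminotransferase genes TAA1 (log2 fold change 2.77, SE 0.302, adjusted p = 0.0262) and TAR2 (log2 fold change 3.13, SE 0.425, adjusted p = 0.0339) of indole-3-pyruvate synthesis. The list as a whole lay higher than other genes (camera adjusted p = 0.0480, and adjusted p = 0.655 with an estimated correlation). That call ended with adjusted p = 0.225 without WT replicate 1, adjusted p = 0.108 without arr1 replicate 2 and adjusted p = 0.0557 without Pro35SARR1 replicate 1. IAA17, an auxin-response repressor, was at 129.7 ± 6.23 CPM against 293 ± 63.6 CPM in WT and was not called (log2 fold change −1.18, SE 0.210, adjusted p = 0.0508), while the block gave adjusted p = 0.00497. No other Aux/IAA gene among 19 detected was called, and 1 was lower adjusted over the list alone and 1 higher and 2 lower with the block. The Aux/IAA list passed as higher with adjusted p = 0.0359 without WT replicate 2.

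Of 46 detected photosynthesis genes 40 lay below 0, with a median log2 fold change of −0.44 (−0.31 scaled by totals alone), and the list lay lower than other genes (camera adjusted p = 2.30e-05, and adjusted p = 0.655 with an estimated correlation). Only 2 members passed on their own, 3 adjusted over the list alone and 23 with the block. The 2 were the photosystem II genes PSBO2 (log2 fold change −1.09, SE 0.158, adjusted p = 0.0372) and PSBQ2 (log2 fold change −0.75, SE 0.128, adjusted p = 0.0473). Of 37 cell cycle genes 1 rose, the D-type cyclin CYCD3;2 (log2 fold change 1.103, SE 0.0944, adjusted p = 0.0219), and adjusted over the list alone 4 were higher and 1 lower, against 6 higher and 3 lower with the block (camera adjusted p = 0.0354, and adjusted p = 0.655 with an estimated correlation). The list's call ended with adjusted p = 0.133 without WT replicate 1, adjusted p = 0.144 without arr1 replicate 1 and adjusted p = 0.0557 without Pro35SARR1 replicate 1. In the flavonoid list 2 of 8 rose, the late anthocyanin genes DFR (3.203 ± 0.343 CPM against 0.169 ± 0.0792 CPM, adjusted p = 0.0461) and LDOX (5.20 ± 2.64 CPM against 0.169 ± 0.0800 CPM, adjusted p = 0.0372), while 6 were lower and 2 higher adjusted over the list alone, against 2 higher and 3 lower with the block. The flavonoid list passed as lower with adjusted p = 0.0393 without arr1 replicate 2. ACR4, a receptor kinase gene, was the 1 member called of 12 in the root meristem and callus list (log2 fold change 1.149, SE 0.193, adjusted p = 0.0468), against 2 higher with the block.

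No member was called in the libraries labelled arr1 in the other lists, given with their median log2 fold change: type-B response regulators (6 detected, median 0.16), root hair (7 detected, median −0.94, with the block 3 lower), endodermis (4 detected, median −0.50), xylem and phloem (10 detected, median −0.43, with the block 2 lower), salicylate and defence (15 detected, median −0.20, with the block 1 higher), jasmonate (10 detected, median −0.094, with the block 1 higher), abscisic acid and cold (8 detected, median 0.36, with the block 1 lower) and hypoxia (9 detected, median −0.080, with the block 2 lower). With the block, camera placed the root hair list (adjusted p = 0.0332) and the xylem and phloem list (adjusted p = 0.0275) lower. With an estimated correlation both calls ended (adjusted p = 0.539 and adjusted p = 0.539). For the root hair list the estimate (−0.11) lay under the preset 0.01, so a higher correlation did not end its call. For the xylem and phloem list the estimate was 0.082. Without 1 library the xylem and phloem list passed as lower (adjusted p = 0.00897 without WT replicate 1), as did the hypoxia list (adjusted p = 0.0189 without arr1 replicate 2). Without normalization factors the medians of the jasmonate and hypoxia lists changed sign, to 0.030 and 0.056. The mean differed in sign from the median and the list test for the salicylate list (mean 0.12, median −0.33 with low members at their bound) and the flavonoid list (mean 0.25, median −0.78).

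The largest changes among genes whose libraries did not overlap included genes with no counts in one genotype. AT2G10940 and AT1G28410 had no counts in WT and were at least 52.1-fold and at least 24.1-fold higher in the libraries labelled arr1, against a floor of 3 counts per library. AT2G10940 was at 10.7 and 24.5 CPM there (adjusted p = 0.0477), and its bound was 31.6-fold without arr1 replicate 2. SUVR1, which encodes a SET-domain protein, was at least 19.8-fold higher. TGG1, a myrosinase gene, stood at 24.9 and 213 CPM in the 2 libraries labelled arr1 and 0.225 CPM on average in WT (adjusted p = 0.0485). MRD1 had no counts in either library labelled arr1 and was at least 29.03-fold lower than its 9.96 ± 1.81 CPM in WT. It overlaps another locus, so its reads may have been counted there. AT5G47980 fell from 36.0 ± 2.79 CPM to 2.00 ± 0.0933 CPM (log2 fold change −4.16, SE 0.143, adjusted p = 0.00323). AT1G34520 fell from 19.2 ± 5.69 CPM to 0.570 ± 0.643 CPM (adjusted p = 0.0318) and AT3G27970 from 8.28 ± 1.05 CPM to 0.172 ± 0.244 CPM (adjusted p = 0.0442). Of 2 unannotated loci, the one on chromosome 1 (28515250 to 28515917) was at 13.0 ± 1.78 CPM in the libraries labelled arr1 and 0.0564 ± 0.0797 CPM in WT (adjusted p = 0.0219). The one on chromosome 3 (4285659 to 4288871) was at 0.457 ± 0.159 CPM against 14.0 ± 8.57 CPM (adjusted p = 0.0318).

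The authors' deposited table of arr1 against WT lists 437 genes, 260 up and 177 down in arr1. Of these, 428 were tested here, 428 had the same sign and 283 were called with it. DESeq2 called 394 with the same sign and the replicate block 411. With 1 library left out the count lay between 0 and 32, and it was 0 without arr1 replicate 1 and 0 without arr1 replicate 2. The authors' deposited summary gives 177 up and 260 down for arr1, the reverse of the table. The direction of the table is that of its own values, since all 260 genes listed as up had the higher mean in the libraries labelled arr1. The authors set apart 6 auxin, 4 YABBY and 7 growth-regulating factor (GRF) pathway genes from these libraries, so their direction is not independent evidence. Here 4, 3 and 6 of them were called, and 6, 4 and 7 with the block, which added DFL2 (adjusted p = 0.0155), IAA17, YAB5 (adjusted p = 0.0127) and GRF4 (adjusted p = 0.0149). In the GRF set, GRF5 was at 19.7 ± 2.06 CPM against 0.225 ± 0.318 CPM in WT (adjusted p = 0.0264). GRF3 was at 50.02 ± 3.97 CPM against 12.1 ± 2.44 CPM (adjusted p = 0.0219) and AN3, a coactivator of GRFs, at 57.6 ± 20.17 CPM against 9.74 ± 1.53 CPM (adjusted p = 0.0361). In the auxin set ARF18 was higher (log2 fold change 2.58, SE 0.328, adjusted p = 0.0318) and AT2G36210 lower (log2 fold change −1.67, SE 0.254, adjusted p = 0.0408).

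The comparison of Pro35SARR1 with WT asked what ARR1 driven by the 35S promoter does. After ARR1 itself, the higher genes included IND, a basic helix-loop-helix gene known from fruit opening (24.1 ± 7.66 CPM against 0.113 ± 0.000246 CPM in WT, adjusted p = 0.0274). Its WT mean lay under the floor of 0.338 CPM. They also included RNS1, a secreted ribonuclease gene (85.8 ± 13.5 CPM against 1.58 ± 0.640 CPM, log2 fold change 5.75, SE 0.284, adjusted p = 0.00704). The cellulase gene CEL3 rose from 27.5 ± 8.70 CPM to 579 ± 87.5 CPM (log2 fold change 4.397, SE 0.360, adjusted p = 0.0319). The cell wall invertase gene ATBFRUCT1 rose from 129.6 ± 9.36 CPM to 536 ± 17.4 CPM (log2 fold change 2.05, SE 0.103, adjusted p = 0.00704). The camalexin synthesis gene PAD3 rose from 12.8 ± 2.34 CPM to 67.2 ± 4.46 CPM (log2 fold change 2.39, SE 0.188, adjusted p = 0.0274). CYP71A12, of the same pathway, rose from 1.69 ± 0.322 CPM to 23.0 ± 0.814 CPM (log2 fold change 3.76, SE 0.240, adjusted p = 0.0188).

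In all 16 genes were higher and 0 lower in Pro35SARR1 (edgeR quasi-likelihood test). At an unadjusted p under 0.05, lower genes numbered 872 and higher genes 890, a level that many unchanged genes also pass among 18083 tested. DESeq2 called 80 lower and 190 higher, and limma on log2(FPKM + 1) called 2 lower. With the replicate block 214 were higher and 161 lower, and all 16 calls remained. With 1 library left out the counts were 3 and 0 without WT replicate 1, 4 and 0 without WT replicate 2, 2 and 0 without arr1 replicate 1, 2 and 0 without arr1 replicate 2, 1 and 0 without Pro35SARR1 replicate 1 and 1 and 0 without Pro35SARR1 replicate 2. The authors' deposited summary gives 129 up and 6 down under a second heading that again reads as arr1, and their total of 135 is the number of genes for WT against Pro35SARR1 in the authors' deposited pathway sheet. The direction that up stands for there was not given, and for arr1 the authors' deposited summary and table are the reverse of each other. In DESeq2 here, calls of at least 2-fold were 154 higher and 18 lower in Pro35SARR1. With the larger number given as up, up there more likely stands for higher in Pro35SARR1. The other higher genes had log2 fold changes of 4.73 (AT2G39980), 4.71 (AT4G22050), 3.402 (AT2G43480), 2.99 (YSL7), 2.28 (AGP24), 2.25 (AAT1), 1.60 (AT5G47980), 1.36 (PMAT2) and 1.28 (CXE17), with SEs from 0.107 to 0.358.

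All 46 detected photosynthesis genes lay below 0 in Pro35SARR1, with a median log2 fold change of −0.72, and the list lay lower than other genes (camera adjusted p = 4.82e-28, and adjusted p = 0.621 with an estimated correlation). None was called over all genes, while 36 were lower adjusted over the list alone, 16 in DESeq2 and 28 with the block, and 36 had an unadjusted p under 0.05. The photosynthesis list also lay lower in arr1 (median −0.44). Both comparisons share the WT libraries, so high values in WT cannot be told apart from a fall in both genotypes. Compared directly, it lay lower in Pro35SARR1 than in arr1 (median −0.32). Its members moved together (estimated correlation 0.39), so the 46 genes are not independent observations. The salicylate and defence list lay higher. All 15 detected members lay above 0, with a median of 1.72 (camera adjusted p = 3.98e-14, and adjusted p = 0.594 with an estimated correlation). Its 1 called member was PAD3, with 11 higher adjusted over the list alone and 4 with the block. Of the type-A response regulators 9 of 10 lay above 0 (median 0.45, camera adjusted p = 0.000338, and adjusted p = 0.594 with an estimated correlation). None was called, 3 were higher adjusted over the list alone, 2 in DESeq2 and 2 with the block. ARR5 was at 199 ± 4.61 CPM against 152 ± 9.06 CPM in WT (adjusted p = 0.302), ARR7 at 50.5 ± 7.71 CPM against 38.7 ± 9.47 CPM (adjusted p = 0.618) and ARR15 at 17.3 ± 7.91 CPM against 7.31 ± 4.60 CPM (adjusted p = 0.521).

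The root hair list (median 1.104, camera adjusted p = 0.0174, and adjusted p = 0.655 with an estimated correlation) and the cell cycle list (median 0.15, camera adjusted p = 0.0354, and adjusted p = 0.655 with an estimated correlation) also lay higher, with no member called and 1 of the root hair list higher with the block. The cell cycle list also lay higher in arr1 (median 0.17), and camera did not separate Pro35SARR1 from arr1 (median −0.0050, camera adjusted p = 0.605). Both comparisons share the WT libraries, so low values in WT cannot be told apart from a rise in both genotypes. The root hair call ended with adjusted p = 0.296 without WT replicate 1 and adjusted p = 0.346 without Pro35SARR1 replicate 2. The cell cycle call ended with adjusted p = 0.242 without WT replicate 1, adjusted p = 0.0811 without Pro35SARR1 replicate 1 and adjusted p = 0.0832 without Pro35SARR1 replicate 2. The block added the hypoxia list (adjusted p = 0.00150) and the jasmonate list (adjusted p = 0.0480), both higher, with adjusted p = 0.539 and adjusted p = 0.706 once the correlation was estimated. Without 1 library the hypoxia list passed as higher (adjusted p = 0.00215 without WT replicate 2, adjusted p = 0.0213 without arr1 replicate 1, adjusted p = 0.0182 without arr1 replicate 2 and adjusted p = 0.00970 without Pro35SARR1 replicate 1), as did the jasmonate list (adjusted p = 0.0214 without WT replicate 2, adjusted p = 0.0393 without arr1 replicate 2 and adjusted p = 0.00919 without Pro35SARR1 replicate 2), and the Aux/IAA list passed as lower (adjusted p = 0.0115 without WT replicate 1). Root hair genes also differed between replicates. The 4 members above 5 CPM were higher in replicate 2 by a median log2 difference of 1.55 in WT, 1.53 in arr1 and 1.92 in Pro35SARR1. WUS was at 35.2 ± 8.28 CPM against 9.91 ± 5.59 CPM in WT and was not called (log2 fold change 1.83, SE 0.460, adjusted p = 0.305), while the block gave adjusted p = 0.0297. IAA17 was at 489 ± 106 CPM (log2 fold change 0.74, SE 0.207, adjusted p = 0.348, and with the block adjusted p = 0.0400). STM was at 5.46 ± 1.12 CPM (adjusted p = 0.806). In the type-B list ARR1 was the 1 member called of 6. The remaining lists held no called member, with these median log2 fold changes: cytokinin metabolism and transduction (31 detected, median 0.0095, with the block 4 higher and 1 lower), shoot meristem and shoot regeneration (21 detected, median 0.0013, with the block 1 higher), leaf polarity and lateral organ (10 detected, median −0.017), root meristem and callus identity (12 detected, median −0.16), Aux/IAA repressors (19 detected, median −0.15, with the block 1 higher), auxin synthesis, transport and conjugation (22 detected, median −0.12), endodermis (4 detected, median −0.89), xylem and phloem (10 detected, median −0.15), abscisic acid and cold (8 detected, median 0.18) and flavonoid and anthocyanin (8 detected, median 0.13). With low members at their bound the medians of the shoot meristem and leaf polarity lists were −0.023 and −0.055. Scaled by totals alone, the leaf polarity median changed sign (0.00047). Means of the type-B (0.74; median −0.017), leaf polarity (0.022) and xylem and phloem (0.13) lists differed in sign from their medians.

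**Figure D2:**
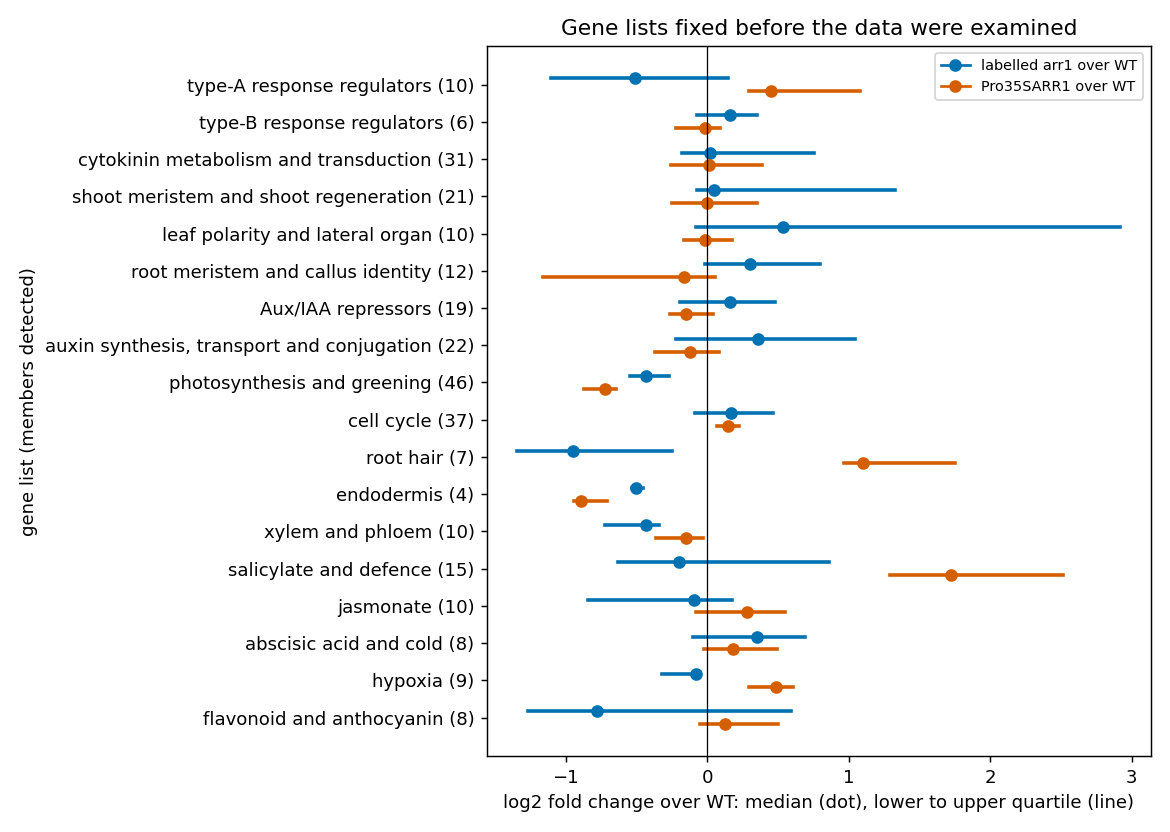
Median log2 fold change over WT (dots) and lower to upper quartile (lines) of the members of 18 gene lists, for the libraries labelled arr1 and for Pro35SARR1. The photosynthesis list has medians of −0.44 and −0.72, the type-A response regulators −0.51 and 0.45, and the salicylate and defence list −0.20 and 1.72.

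The direct comparison of Pro35SARR1 with the libraries labelled arr1 set the 2 ARR1 genotypes side by side. ARR5 was 2.44-fold higher in Pro35SARR1 (log2 fold change 1.29, SE 0.0996, adjusted p = 0.00930), IAA17 was 3.77-fold higher (log2 fold change 1.92, SE 0.214, adjusted p = 0.0156) and STM was lower (log2 fold change −2.06, SE 0.326, adjusted p = 0.0289). WUS was not called (log2 fold change 2.09, SE 0.467, adjusted p = 0.0594), and the block gave adjusted p = 0.00341. ARR7, ARR15, ARR10 and ARR12 were not called, with log2 fold changes of −0.33 (SE 0.201), 0.65 (SE 0.500), −0.18 (SE 0.215) and 0.15 (SE 0.133). ARR1 itself had a log2 fold change of 4.92 (SE 0.117). In all 739 genes were higher and 431 lower in Pro35SARR1 (edgeR quasi-likelihood test), 63.2% of calls higher against 46.7% when scaled by library totals alone, which moved the median log2 fold change by −0.11. The block gave 2084 and 1595. With 1 library left out the counts were 700 and 382 without WT replicate 1, 684 and 368 without WT replicate 2, 7 and 1 without arr1 replicate 1, 5 and 0 without arr1 replicate 2, 27 and 13 without Pro35SARR1 replicate 1 and 23 and 12 without Pro35SARR1 replicate 2.

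Of the type-A response regulators 5 of 10 were higher in Pro35SARR1 than in the libraries labelled arr1, and 5 adjusted over the list alone (camera adjusted p = 0.00560, and adjusted p = 0.621 with an estimated correlation). The salicylate and defence list had 4 of 15 members higher, 12 adjusted over the list alone, 8 in DESeq2 and 12 with the block (camera adjusted p = 1.82e-06, and adjusted p = 0.621 with an estimated correlation). The photosynthesis list had 2 lower of 46, 4 adjusted over the list alone and 15 with the block (camera adjusted p = 2.30e-05, and adjusted p = 0.655 with an estimated correlation), and that call ended with adjusted p = 0.0618 without Pro35SARR1 replicate 1. The auxin synthesis, transport and conjugation list had 3 lower of 22, 3 lower and 1 higher adjusted over the list alone and 1 higher and 10 lower with the block (camera adjusted p = 0.0191, and adjusted p = 0.655 with an estimated correlation), and its call ended with adjusted p = 0.0961 without Pro35SARR1 replicate 1. The leaf polarity list had 2 lower of 10, 4 lower and 1 higher adjusted over the list alone and 1 higher and 4 lower with the block (camera adjusted p = 0.0354, and adjusted p = 0.655 with an estimated correlation), and its call ended with adjusted p = 0.0806 without arr1 replicate 1 and adjusted p = 0.0961 without Pro35SARR1 replicate 1. The root hair list had no called member of 7, 1 higher adjusted over the list alone, 2 in DESeq2 and 6 with the block (camera adjusted p = 0.0162, and adjusted p = 0.655 with an estimated correlation), and its call ended with adjusted p = 0.0882 without arr1 replicate 1 and adjusted p = 0.102 without Pro35SARR1 replicate 2. The block added the hypoxia list, higher in Pro35SARR1 (adjusted p = 0.00205, and adjusted p = 0.539 with an estimated correlation). It also passed with adjusted p = 0.0454 without WT replicate 1, adjusted p = 0.0287 without WT replicate 2, adjusted p = 0.000691 without arr1 replicate 2 and adjusted p = 0.0180 without Pro35SARR1 replicate 1. Other lists passed only with 1 library left out. They were the jasmonate list as higher (adjusted p = 0.0393 without arr1 replicate 2 and adjusted p = 0.0150 without Pro35SARR1 replicate 2), the flavonoid list as higher (adjusted p = 0.0393 without arr1 replicate 2), the root meristem and callus list as lower (adjusted p = 0.0393 without arr1 replicate 2) and the shoot meristem list as lower (adjusted p = 0.0471 without arr1 replicate 2 and adjusted p = 0.0479 without Pro35SARR1 replicate 2).

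Both comparisons use the same WT libraries. Between them 7 genes were called lower in the libraries labelled arr1 and higher in Pro35SARR1, where independent lists of these sizes would share 0.303. Simulated unchanged groups shared 0, which is no measure of chance for the 7, since they gave on average only 0.200 and 0.250 calls per simulation. The 7 were AT5G47980, AT4G22050, AT2G43480, the invertase gene ATBFRUCT1, the acyltransferase gene PMAT2, the carboxylesterase gene CXE17 and the arabinogalactan protein gene AGP24. ATBFRUCT1, for example, stood at 71.8 ± 2.303 CPM in the libraries labelled arr1 (log2 fold change −0.85, SE 0.101, adjusted p = 0.0287), and PMAT2 at 22.0 ± 1.92 CPM (log2 fold change −1.32, SE 0.110, adjusted p = 0.0219). In the edgeR test without the block 0 genes were called in both in the same direction (independent lists would share 0.175 higher in both and 0 lower). Same-direction calls appeared under other settings. The block gave 73 genes lower in arr1 and higher in Pro35SARR1 (independent lists 20.4), 111 lower in both (15.3), 22 higher in both (13.3) and 5 the reverse (10.0). DESeq2 gave 39 (7.63), 35 (3.21), 15 (3.98) and 2 (1.68) in the same order. Under both settings the count lower in both genotypes stood farthest, as a ratio, above that of independent lists. Those ratios are no fair measure, since shared WT libraries move both comparisons the same way. Independent lists thus set the bar too low for same-direction counts and too high for opposite ones. The overlaps under these settings were not simulated. Limma on FPKM called 2 lower in both, AT1G52857 and ATCG00630, with at most 1.88 estimated counts in a library, and leaving out WT replicate 2 gave 1 higher in both, ORP2A. The 2 the reverse in DESeq2 were AT2G33830 and ABCB2, and the block added DYL1, AT5G24490 and BT1, all named after their values were seen. With 1 library left out the 7 were no longer called in both comparisons. That is a weak check on them. Such fits have fewer residual degrees of freedom and lost most calls in both comparisons with WT, also where the library belonged to the third genotype. Over 18083 genes the covariance of the log2 fold changes was 0.158, against 0.0981 (SD 0.00581 over 40 simulations) from shared controls alone when libraries were simulated as independent, a difference of 0.0598. With the deviations shared by replicate number kept, the simulated covariance was 0.0602 (SD 0.00411), a difference of 0.0977. Pearson's r across genes, which are not independent replicates, was 0.258 against 0.497 simulated as independent and 0.495 with the replicate deviations. The WT libraries were not split between the comparisons, since each comparison would keep 1 of them, so part of any excess in the same direction may come from the shared controls.

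**Figure D3:**
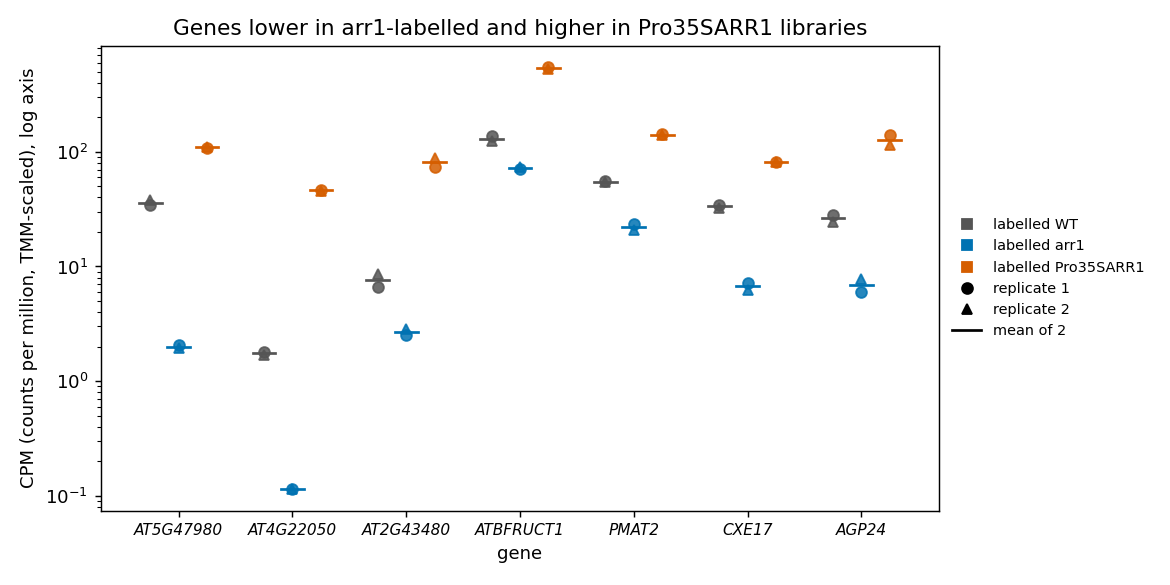
CPM on a log axis per library for the 7 genes called lower in the libraries labelled arr1 and higher in Pro35SARR1 than in WT, with a line at the mean of 2 libraries. AT4G22050 is at 0.114 CPM in the libraries labelled arr1, 1.75 CPM in WT and 46.0 CPM in Pro35SARR1.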

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

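The counts of called genes depended on the processing more than the directions of named genes did, and the cause was not tested unless given. Scaling by totals alone, counts divided by the step and the block with an estimated correlation were chosen after seeing the data. For arr1 against WT the DESeq2 Wald test called 468 higher and 897 lower, no filter 120 higher and 192 lower, the replicate block 1127 higher and 1720 lower, isoforms 10 higher and 7 lower, the 2 genotypes alone 57 higher and 39 lower, a log2 fold change of at least 1 left 169 higher and 152 lower, and totals alone 218 higher and 128 lower, so that lower calls no longer outnumbered higher ones under the last 2, nor with isoforms, the 2 genotypes alone or 1 library left out. For Pro35SARR1 against WT DESeq2 called 190 higher and 80 lower, the block 214 higher and 161 lower, isoforms 8 higher and 1 lower, limma on FPKM 27 higher and 2 lower, and the 2 genotypes alone 2 higher and 0 lower. For Pro35SARR1 against arr1 DESeq2 called 1163 higher and 675 lower, the block 2084 higher and 1595 lower, isoforms 310 higher and 118 lower, no filter 551 higher and 275 lower, and a log2 fold change of at least 1 left 375 higher and 291 lower. The filter and isoform fits test more features, and the fits of 2 genotypes have fewer samples. Leaving out 1 library gave 0 to 26 higher and 0 to 11 lower in arr1 against WT, 1 to 4 and 0 to 0 in Pro35SARR1 against WT, and 5 to 700 and 0 to 382 in Pro35SARR1 against arr1. The lone library left is assumed to vary like the other groups. These fits have fewer residual degrees of freedom. They lost most calls in both comparisons with WT, also where the library left out belonged to the third genotype. A call lost there does not show that it rested on that library. Most calls of named genes that were lost came from these fits. Of the gene lists, 3, 5 and 6 were past the threshold in the 3 comparisons. With an estimated correlation 0, 0 and 0 passed (likewise 0 with the block as well). The block gave 5 in arr1 against WT, and the numbers also moved without 1 library. With fry 1 and 3 passed in the comparisons with WT, and 4 in Pro35SARR1 against arr1. In arr1 it was the root meristem and callus list, as higher (adjusted p = 0.0219), and no list called by camera there passed fry. In Pro35SARR1 they were the type-A list (adjusted p = 0.0219), the salicylate list (adjusted p = 0.0227) and the type-B list (adjusted p = 0.00841). The type-B list holds ARR1 itself. The photosynthesis list in Pro35SARR1 against WT did not pass fry (adjusted p = 0.0736). Against arr1, fry passed the type-A (adjusted p = 0.0149), salicylate (adjusted p = 0.0227) and type-B lists (adjusted p = 0.00841) as higher. It passed the root meristem and callus list as lower (adjusted p = 0.0219). Of camera's calls there, photosynthesis (adjusted p = 0.271), auxin synthesis (adjusted p = 0.129), leaf polarity (adjusted p = 0.0731) and root hair (adjusted p = 0.271) did not pass fry. The genes lower in arr1 and higher in Pro35SARR1 numbered 39 in DESeq2 (lower in both 35, higher in both 15), 73 with the block (lower in both 111, higher in both 22), 7 with limma on FPKM (lower in both 2), 2 isoforms, 0 with 2 genotypes and 0 to 0 without 1 library (higher in both 1 without WT replicate 2). Of the authors' deposited arr1 genes 92 were called with 2 genotypes and 0 to 32 without 1 library. Over 100 named gene comparisons and 1500 alternative values, 1023 kept direction and side of the threshold, 437 lost the call, 30 gained it and 10 changed sign. Those that changed sign were not called in the first place. Without 1 library, log2 fold changes against WT ran from −0.047 to 0.016 for ARR1, −0.29 to 0.11 for ARR10 and −0.76 to 0.46 for WUS in arr1, and −0.17 to 0.050 for ARR12 in Pro35SARR1, while ARR10 in Pro35SARR1 over arr1 ran from −0.39 to 0.015. By totals alone ARR1 in arr1 was at 0.11 and ARR10 at 0.031. Without 1 library the sign turned for ARR1 at 0.016 (arr1 replicate 2), ARR10 at 0.11 (WT replicate 1) and 0.055 (arr1 replicate 2), WUS at 0.46 (WT replicate 1) and 0.077 (arr1 replicate 2), ARR12 at 0.050 (WT replicate 1) and 0.0090 (Pro35SARR1 replicate 2). Apart from the blocked values given beside results, the replicate block changed no other call printed here. Depth limits genes such as CLV3, with at most 4.3 counts in a library.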

Other observations

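The gene names, lists and tests in these paragraphs were chosen after the main results were seen. The depth, root hair and green tissue tests and the reading of linkage by chromosome were chosen after their values had been seen, as was a minimum of 5 genes for deciding the root hair and overlap tests. Outside the fixed lists, genes called in the libraries labelled arr1 and picked for their values included ATML1, PDF1, ER, GL2 and LFY. ATML1, a homeobox gene of the protoderm, was at 51.5 ± 6.55 CPM (SD, n = 2) against 3.43 ± 0.391 CPM in WT (log2 fold change 3.90, SE 0.202, adjusted p = 0.00704), and PDF1 at 455 ± 24.3 CPM against 31.1 ± 16.6 CPM (log2 fold change 3.87, SE 0.400, adjusted p = 0.0247). The receptor kinase gene ER rose from 3.49 ± 1.58 CPM to 102 ± 9.37 CPM (log2 fold change 4.86, SE 0.387, adjusted p = 0.0213) and the trichome regulator GL2 from 0.338 ± 0.160 CPM to 7.08 ± 3.19 CPM (adjusted p = 0.0361). The floral regulator LFY rose from 0.113 ± 0.000246 CPM, under the floor of 0.338 CPM, to 2.52 ± 0.146 CPM (adjusted p = 0.0372). In Pro35SARR1 ATML1 stood at 4.84 ± 0.574 CPM, PDF1 at 36.1 ± 8.70 CPM and ER at 6.18 ± 2.63 CPM.

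In Pro35SARR1 CYP735A1, CKX4 and ARR16 did not pass the test over all genes and did with the replicate block. CYP735A1, of trans-zeatin synthesis, was at 15.3 ± 2.12 CPM against 1.58 ± 0.959 CPM in WT (adjusted p = 0.172, with the block 0.0297). The cytokinin oxidase gene CKX4 was at 15.7 ± 0.127 CPM against 1.75 ± 0.880 CPM (adjusted p = 0.134, with the block 0.0335). The type-A regulator ARR16 was at 84.4 ± 16.2 CPM against 26.2 ± 12.7 CPM (adjusted p = 0.292, with the block 0.0253). Of the 10 type-A regulators 2 passed with the block, and ARR5 (adjusted p = 0.0947), ARR7 (adjusted p = 0.160) and ARR15 (adjusted p = 0.130) did not. Of the 343 genes lower in the libraries labelled arr1, 153 lay above 0 and 190 below 0 in Pro35SARR1, with a median log2 fold change of −0.044. Of the 198 higher genes 125 lay above 0 and 72 below, and 1 at 0, with a median of 0.14. The shares above 0 were 44.6% and 63.1%. Simulations with an unchanged Pro35SARR1, shared WT libraries and the deviations shared by replicate number gave 39.2% (range 32.4% to 44.3%) and 61.4% (range 53.6% to 70.1%), with 321 lower and 254 higher calls on average over 40 simulations. With independent libraries they gave 34.2% (range 30.7% to 38.3%) and 65.8% (range 61.0% to 71.6%). Those had 866 lower and 750 higher calls on average, far more than observed. The observed 44.6% lay above the highest value of either kind, by little with the replicate deviations kept. The observed 63.1% lay within both ranges. The authors' deposited pathway sheet places 7 of 437 arr1 genes and 5 of 135 Pro35SARR1 genes under plant hormone signal transduction, with corrected p-values of 1 and 0.79. In the authors' deposited pathway sheet zeatin biosynthesis holds 0 of 437 and 2 of 135 (corrected p-value 0.20 for Pro35SARR1). Indole alkaloid biosynthesis there holds 2 arr1 genes (authors' deposited corrected p-value 0.20).

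ATML1, PDF1, FIL and YAB3 were higher in the libraries labelled arr1. As a hypothesis, a larger share of shoot epidermis may account for part of these increases. A list of 26 epidermis and cuticle genes, written before its values were looked up, had 5 members called higher and 1 lower of 21 detected (12 higher and 2 lower with the block) and was not tested as a set, while 18 lay above 0, with a median log2 fold change of 1.098, just over the bound of 1 set for it. Against it, GPAT6 was lower (log2 fold change −1.54, SE 0.138, adjusted p = 0.0219), and the most abundant member, the lipid transfer protein gene LTP1, was at 698 ± 74.1 CPM against 469.9 ± 106 CPM in WT (adjusted p = 0.262, with the block 0.0232). FIL and YAB3, which belong to the leaf polarity list, had log2 fold changes of 5.19 and 5.47. A share that rose by no more than the epidermis median would not account for increases of that size. More green tissue as a whole is argued against by the photosynthesis median of −0.44, but weakly. That list lay still lower in Pro35SARR1 (median −0.72), where ATML1 and PDF1 stood near WT, so it can move apart from these genes. Both medians rest on the same WT libraries. A shift of scale is argued against by the epidermis median, which stayed at 0.63 or more under 4 other scalings. Its lowest value, on log2(FPKM + 1), lay under the bound of 1. The 1 added there shrinks changes of genes at low levels, so that value cannot be set against the bound directly. Scaled by totals alone the median was 1.22. Whether the support for a larger epidermis share holds on FPKM is therefore undecided. A change of these genes within the same cells was not tested and stays open.

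Libraries with the same replicate number deviated together in all 3 genotypes. Depth in fragments, the counts divided by the step, is argued against as the cause: replicate 2 had more of them than replicate 1 in WT (10000859 against 8427641) and fewer in Pro35SARR1 (8014081 against 8895088), while the deviations of these genotypes correlated at 0.637 across genes. The deposited totals, which were higher in replicate 2 in all 3 genotypes, are sums after scaling, and trends on gene length and expression level are argued against too, as the lowest of the 3 correlations was 0.393 after they were removed. A different share of root hair cells stays open, since only 4 of its genes passed 5 CPM, and the design names no biological difference between the numbers. The median replicate difference of these genes lay at percentile 100 of 10000 random lists in each genotype, but that of the photosynthesis list was nearly as high (lowest percentile 99.99).

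In same-genotype pairs 4 genes had no counts in both libraries and at least 3 CPM in the other 4 libraries: SUVR1 and AT2G44850 in WT, and MRD1 and SWEET7 in the libraries labelled arr1. A failed estimate in single libraries cannot be told apart, because Pro35SARR1 had 0 such genes and the highest pair of mixed genotypes had 1. Reads counted for an overlapping gene met the bound set for it, with 2 of 4 genes (50%) overlapping another locus against 19.5% of expressed genes, but so few genes leave it undecided. A segment linked to ARR1 is argued against for the genes at 0 in the libraries labelled arr1, since MRD1 and SWEET7 lie on chromosomes 1 and 4 and ARR1 on chromosome 3 (0 of 2 within 5 Mb of it, 1-sided exact binomial p = 1). No sequence was examined, so a difference between the lines at these loci stays open.

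One hypothesis was that ARR1 level sets the triterpene genes together, since AT5G47980 and its neighbour CYP705A5 were lower in the libraries labelled arr1 (CYP705A5 log2 fold change −2.44, SE 0.117, adjusted p = 0.00704). Of 5 further thalianol and marneral synthesis genes, 3 were detected and 2 of them, THAS1 and CYP708A2, were lower in arr1 and higher in Pro35SARR1. THAS1 had log2 fold changes of −1.37 (SE 0.220) and 0.67 (SE 0.213), and CYP708A2 of −1.20 (SE 0.137) and 0.45 (SE 0.134), in arr1 and Pro35SARR1. The increases had adjusted p = 0.392 and adjusted p = 0.372, and with the block adjusted p = 0.0441 and adjusted p = 0.0466. The exception, CYP71A16, was at 2.53 ± 1.52 CPM in WT and 2.08 ± 0.212 CPM in Pro35SARR1, so the test as set left the hypothesis undecided. ARR1 transcript, however, stood at 59.9 ± 1.83 CPM in the libraries labelled arr1 and 60.6 ± 1.09 CPM in WT. That argues against ARR1 transcript level as the cause of the decreases in the libraries labelled arr1. ARR1 protein and activity were not measured, and the increases in Pro35SARR1 stay undecided.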
